A study of Mus musculus with 24 samples.

How the data were processed

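MicroRNA was profiled in 3 mouse mammary carcinoma lines (67NR, 4TO7, 4T1) kept for 6 days in organotypic culture, per the labels, on compliant or rigid microenvironments and with TGF-beta or an inhibitor of the TGF-beta type I receptor. Each of the 12 groups had 2 replicates, named set 1 and set 2 in the labels, on 24 arrays of 5 slides, called slide 1 to slide 5 here. The arrays were 2-dye miRNA arrays that carry 593 probes, 558 for mouse miRNAs and 35 for spike-in controls. Per the file headers, the deposited intensity of each probe is a relative intensity, the sample signal in DY649 over a synthetic reference in DY547. It is on the linear scale, after background subtraction and a correction for labelling made by the authors, and without normalization between arrays. The deposited files also give a percent error of each intensity, a p-value for presence above background (a detection p_value, per the file headers) and a fail code, which marks a spot whose reference channel was below background. The authors' deposited value table holds log2 intensity for 338 probes. It equals the log2 of the deposited relative intensity plus 1 constant per array, with a largest deviation of 5.7e-06, constants between -0.287 and 0.236 and array medians of 8.13 to 8.36. The rule behind the constants and the choice of probes is not given in the sources used here, and neither are the scanner and software versions. Of the probes tested below, 27 are not in that table.

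Depth on arrays is signal over background. The number of probes with a detection p under 0.05 was 313 to 357 of 558 per array, and 174 miRNA probes were detected on no array. The median log2 intensity before normalization was 7.29 to 7.87, that of the spike-in probes 11.8 to 12.1, and the median percent error 5.72 to 9.06. The number of arrays limits the precision of each value. The array annotation names no genome build, so no positions are given. The arrays with the lowest correlation within a group had r = 0.995, and the highest r between arrays of different groups was 0.997. The first 3 principal components of the arrays held 70.5%, 16.2% and 5.52% of the variance.

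The log2 intensities of the 558 miRNA probes were quantile normalized with limma 3.58.1 in R 4.3.3. Probes were kept if they were detected on both arrays of at least 1 group and if the fail code was set on fewer than 12 arrays, which dropped 10 probes and left 365. Of these, 7 carry the names of several miRNAs. A linear model with 12 group means was fitted with lmFit (12 residual degrees of freedom, median residual SD 0.0764), contrasts were averaged over groups with equal weight, and moderated statistics came from eBayes with a mean-variance trend. Two-sided p-values were adjusted by Benjamini and Hochberg over the tested probes of each comparison, and an adjusted p under 0.05 counted as changed. The comparisons were TGF-beta against inhibitor and rigid against compliant, each over all lines and per line, the 3 pairs of lines, and F tests or contrasts for differences of the TGF-beta effect between lines and between microenvironments. An F test for the effect of rigidity between lines was added after the values were seen, which made 14 comparisons, each adjusted on its own. Quantile normalization gave miR-720, miR-1224 and miR-705 the same rank, hence the same value, on every array.

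Gene lists were the miR-181, miR-200, let-7, miR-29, miR-30 and miR-34 families, the miR-183, miR-17, miR-23, Dlk1-Dio3 and Sfmbt2 clusters, the miR-221 and miR-15 groups, and miRNAs reported as TGF-beta induced, as metastasis promoting or as metastasis suppressing. A fibroblast and mesenchymal list was used too. Marker lists of foreign cell types, which the cultures should not hold, covered blood, endothelial, muscle, neural and liver, and embryonic stem cells. Lists of at least 3 tested probes, 18 in each comparison, were tested with camera at its preset correlation of 0.01 and again with an estimated correlation. Each list's adjusted p is over the lists of its comparison. Of 216 pairs of list and comparison, 57 passed with the preset and 6 with the estimated correlation. In 19 of the 216 the median, the mean and the test differed in sign, and none of these passed. List members changed were also counted with p adjusted over the list alone.

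The named miRNAs were, per comparison, the 10 largest rises and 10 largest falls among those with an adjusted p under 0.05 and the same direction in both replicate sets. Where fewer than 3 passed, the largest changes with an unadjusted p under 0.05 were named as values that did not pass. MiR-181a and miR-181b were named everywhere, the 6 smallest p for each difference of effects, and list members with the smallest p as examples. The miRNAs changed in all 3 lines and those detected in 1 line only were named after their values were seen. Where a miRNA was detected on no array of 1 side, the fold is given as a bound against the background level ("at least"), and no fold is given where both sides were below background.

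Each comparison was repeated with median scaling, without the detection filter, with detection on at least 12 arrays required (335 probes), with the authors' value table, with slide as a fixed or random block, with set number as a replicate block over all lines or within each line, with array weights, with only the lines compared, and without each array in turn. Median scaling over the 282 probes detected on all arrays, and keeping fail-coded probes (367 tested), were chosen after seeing the data. Background correction was not varied since the deposited values are already corrected, and the arrays hold no miRNA probes of other species. In 4T1, residuals of arrays with the same set number were correlated above 0.1 in 6 of 6 pairs of groups (0.23 to 0.49), so the values with a replicate block are given with the alternatives. Spike-in probes were fitted the same way, and among 32 detected on all arrays 0, 0, 5, 3 and 0 passed for TGF-beta, rigidity, 4TO7 against 67NR, 4T1 against 67NR and 4T1 against 4TO7.

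The procedure was tested on simulated data of the same design. Of changes of log2 0.25 in 365 simulated miRNAs, 97.1% were recovered over all lines, 94.1% in 4T1 and 67.6% by the F test between lines, and all changes of log2 0.5 and 1 were recovered, with 4, 9 and 4 false calls among 265 unchanged. The list test recovered the changed list with 0 false calls among 17. The simulated noise was independent between miRNAs, so this does not measure false list calls where miRNAs are correlated. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.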

Results

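MicroRNA levels were measured on 24 arrays of 3 mouse mammary carcinoma lines, sister lines that the labels describe as nonmetastatic (67NR), systemically invasive (4TO7) and highly metastatic (4T1). Cells of each line had grown for 6 days in organotypic cultures whose microenvironment was either compliant or rigid. They were treated either with TGF-beta, a growth factor that drives epithelial-mesenchymal transition and fibrosis, or with an inhibitor of the TGF-beta type I receptor, called basal in the labels. No group was left without both, so a rise or fall with TGF-beta below is relative to the inhibitor. An effect of TGF-beta and an opposite effect of the inhibitor cannot be told apart. The 12 combinations of line, microenvironment and treatment had 2 replicate arrays each, spread over 5 slides. Between 313 and 357 mouse miRNA probes were detected on each array, and 365 were tested. Replicate arrays of a group correlated at r = 0.995 to 0.999 across miRNAs, with a replicate SD of 0.07 to 0.13 on the log2 scale. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these arrays only. Values below are log2 differences with their standard error (SE).

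The first question was which miRNAs respond to TGF-beta signalling, asked over all 3 lines with 12 TGF-beta arrays against 12 inhibitor arrays. MiR-181b and miR-181a, which are made from shared precursor transcripts, rose by 0.92 ± 0.02 and 0.88 ± 0.02, or 1.89-fold and 1.84-fold. MiR-22, a widely expressed miRNA, rose by 0.74 ± 0.03. MiR-222 and miR-221, which share a transcript and repress the cell cycle inhibitor p27, both fell by 1.07 (SE 0.03 and 0.05), to 0.476 of their level with the inhibitor. MiR-210, the main hypoxia-induced miRNA, fell by 0.84 ± 0.05, and miR-193 by 0.83 ± 0.04. The rise of miR-181a was seen in each of the 6 pairings of line and microenvironment, between 0.73 and 0.98, as was the fall of miR-222.

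Further rises with TGF-beta were measured for miR-146a (0.58 ± 0.03) and miR-146b (0.40 ± 0.03), which dampen inflammatory NF-kappa-B signalling. They were detected on 6 and 7 of the 12 TGF-beta arrays and on 4 and 5 of the 12 inhibitor arrays. MiR-155, an inflammation-induced miRNA, rose by 0.46 ± 0.03 and miR-21, an oncogenic miRNA raised in many tumours, by 0.45 ± 0.05. MiR-181d rose by 0.41 ± 0.02, let-7i by 0.38 ± 0.03 and miR-34a, a target of the tumour suppressor p53, by 0.36 ± 0.03. Falls were measured for miR-365 (0.63 ± 0.04) and for miR-193b (0.63 ± 0.04), whose genes are neighbours. MiR-125b-5p fell by 0.47 ± 0.04, miR-26a by 0.40 ± 0.03, miR-31* by 0.38 ± 0.02 and miR-100 by 0.37 ± 0.03. Adjusted p-values of these 20 miRNAs lay between 1.5e-14 and 1.6e-06 in limma. In all, 78 miRNAs rose and 66 fell of the 365 tested, and only 2 of the 144 changed more than 2-fold, miR-221 and miR-222. The balance of rises and falls moved with the scaling between arrays, to 43 and 84 under median scaling, 110 and 50 in the authors' value table, and 93 and 53 under median scaling over probes detected on all arrays.

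**Figure D1:**
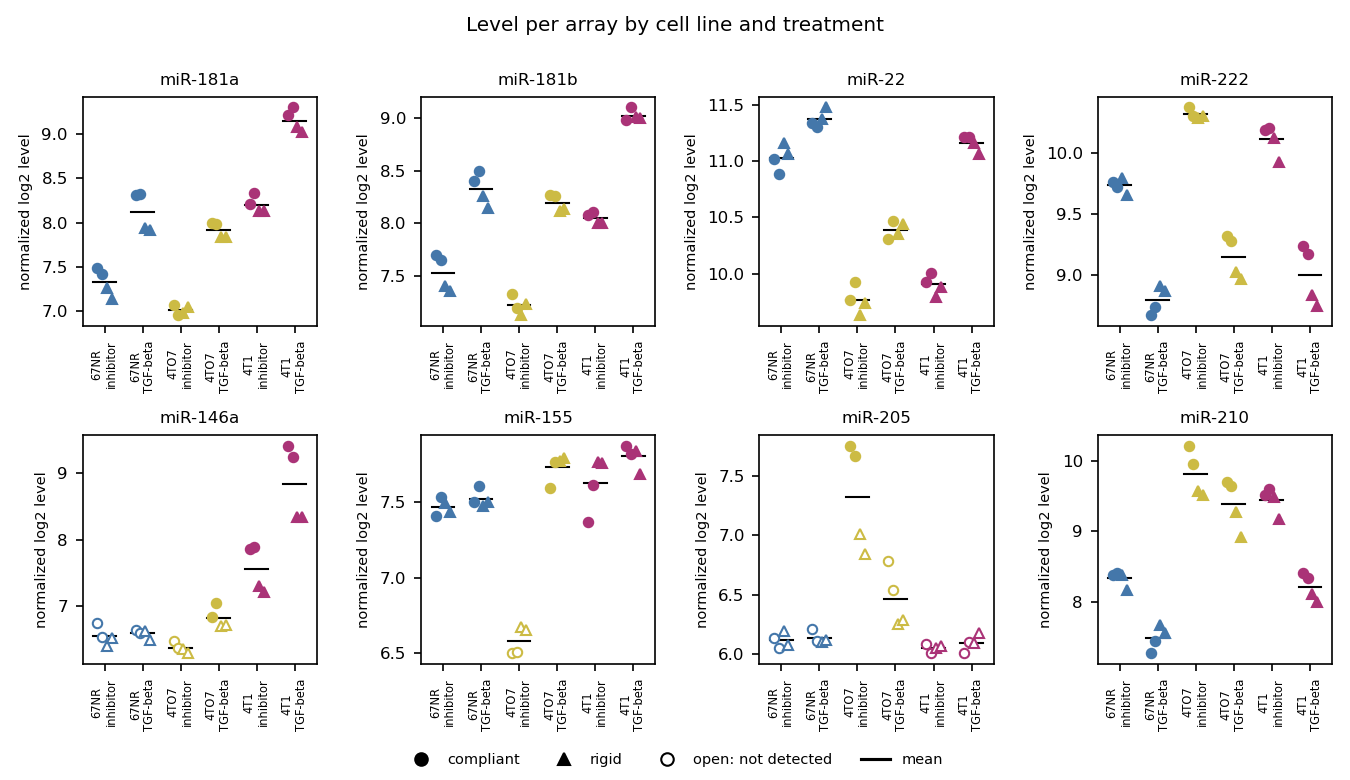
Normalized log2 level of 8 miRNAs by line and treatment, with 1 point per array (circles compliant, triangles rigid, open symbols not detected) and a bar at the mean. With TGF-beta miR-181a rose by 0.79 in 67NR, 0.90 in 4TO7 and 0.95 in 4T1, while miR-222 fell by 0.94, 1.17 and 1.11.

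Gene groups fixed before the data were examined, as were the tests and the rule for naming miRNAs, moved as follows with TGF-beta. In the miR-181 family 3 of 4 members rose and miR-181c fell by 0.08 ± 0.02 (median 0.64, camera adjusted p = 0.0025, or adjusted p = 0.18 with an estimated correlation). The published study of these samples chose this family, so its count is not independent evidence. The fall of miR-181c was not called in the authors' value table or under median scaling over probes detected on all arrays. All 5 measured members of the miR-30 family, linked to mammary differentiation, fell, among them miR-30a by 0.32 and miR-30d by 0.26 (median -0.30, adjusted p = 0.0020, or adjusted p = 0.16 with an estimated correlation). In the miR-221 and miR-15 groups of cell cycle regulators 6 of 8 fell and none rose, among them miR-15b by 0.29 and miR-322 by 0.20 (median -0.22, adjusted p = 0.00096, or adjusted p = 0.16 with an estimated correlation). Of 9 let-7 family members, which oppose proliferation, 6 fell and let-7i rose, with 7 falls and 1 rise when adjusted over the list alone (median -0.23, adjusted p = 0.030, or adjusted p = 0.60 with an estimated correlation). Among 8 measured miRNAs reported elsewhere as TGF-beta induced, miR-155, miR-21 and miR-199a-5p rose and none fell (median 0.07, adjusted p = 0.030, or adjusted p = 0.16 with an estimated correlation). Of 15 Sfmbt2 cluster miRNAs, a rodent family in an intron of Sfmbt2, 4 fell and none rose (median -0.07, adjusted p = 0.030, or adjusted p = 0.60 with an estimated correlation). That last call was lost in the authors' value table (adjusted p = 0.12) and under median scaling over probes detected on all arrays (adjusted p = 0.082). With slide as a block the let-7 and TGF-beta induced lists had an adjusted p of 0.052 each, and without the detection filter the TGF-beta induced list had 0.14.

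The other lists did not pass the list test for TGF-beta. In the miR-34 family 4 of 6 rose, in the Dlk1-Dio3 cluster, a large imprinted miRNA cluster, 9 of 30 rose and 1 fell, and in the miR-183 cluster miR-182 (0.16) and miR-183 (0.12) rose. Adjusted over the list alone, 8 Dlk1-Dio3 members rose and 1 fell. Of 13 members of the miR-17 clusters 3 fell (2 when adjusted over the list alone), of 5 miR-200 family members 1 rose (0 alone), of 3 in the miR-29 family 1 fell (2 alone), and of 3 in the miR-23 clusters none passed. The metastasis lists moved both ways, with 2 of 8 reported promoting members higher and 3 lower, and 3 of 9 reported suppressing members higher and 4 lower. The fibroblast and mesenchymal list and markers of foreign cell types were checked too. In the fibroblast and mesenchymal list 1 of 6 rose (miR-199a-5p, 0.10), in the neural and liver list 0 of 6 passed, and in the embryonic stem cell clusters 2 of 6 rose (miR-290-5p, 0.20). The muscle miRNAs miR-208b and miR-206 fell by 0.23 and 0.06, the blood miRNA miR-451 differed by 0.06 without passing, and none of the 2 endothelial probes passed the detection filter.

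Slides held few matched pairs. TGF-beta and inhibitor arrays of the same line and microenvironment shared a slide in 4 cases, 1 each in compliant and rigid 67NR and in compliant and rigid 4TO7, and in none for 4T1. Within those slides miR-181a rose by 0.82, 0.65, 1.03 and 0.82, and 78.5% to 86.8% of the 144 changed miRNAs moved in the same direction. With slide as a fixed block all 20 named miRNAs passed with the same sign (miR-181a 0.87, miR-222 -1.08), and 107 miRNAs passed in all, 49 higher and 58 lower. MiR-146a, miR-21, miR-146b, let-7i and miR-34a were the named miRNAs whose sign differed within at least 1 of the 4 slide pairs, with lowest values of -0.11, -0.14, -0.02, -0.07 and -0.04. List medians under the slide block were 0.64 for the miR-181 family (0.53 to 0.77 within slides), -0.26 for miR-30 (-0.30 to -0.18), -0.20 for the miR-221 and miR-15 groups (-0.36 to -0.19), -0.23 for let-7 (-0.28 to 0.02), 0.06 for the TGF-beta induced list (0.03 to 0.09) and -0.10 for the Sfmbt2 cluster (-0.10 to 0.09). Over the 4 slide pairs the Sfmbt2 values had a median of 0.04, opposite in sign to the called fall.

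In 67NR, with 4 arrays against 4, miR-181b was 0.80 ± 0.04 higher with TGF-beta than with the inhibitor. MiR-181a was higher by 0.79 ± 0.04, miR-181d by 0.37 ± 0.04 and miR-22 by 0.34 ± 0.06. MiR-221 fell by 0.97 ± 0.09 and miR-222 by 0.94 ± 0.05, followed by miR-193 (0.92), miR-210 (0.85), miR-125b-5p (0.72), miR-193b (0.69), miR-365 (0.59) and miR-31 (0.59), a reported suppressor of breast cancer metastasis. MiR-130a and miR-484 fell by 0.41 and 0.40. Smaller rises were those of miR-350 (0.22), miR-673-3p (0.21), miR-551b (0.20), miR-9 (0.17), miR-33 (0.16) and miR-17* (0.13). Altogether 12 miRNAs rose and 28 fell, and none changed 2-fold. Scaling moved this split to 5 and 41 under median scaling, 35 and 26 in the authors' value table, and 17 and 22 under median scaling over probes detected on all arrays. The count of 40 became 63 with array weights and 70 with set number within each line as a block. Besides the miR-181 family (3 of 4 higher, 1 lower, median 0.58, adjusted p = 0.00050, or adjusted p = 0.18 with an estimated correlation), 4 lists fell. The let-7 family had 3 of 9 lower, or 6 adjusted over the list alone (median -0.21, adjusted p = 0.0019, or adjusted p = 0.32 with an estimated correlation). The miR-30 family had 2 of 5 lower, or 3 adjusted over the list alone (adjusted p = 0.0035, or adjusted p = 0.24 with an estimated correlation). The miR-221 and miR-15 groups had 3 of 8 lower, or 4 adjusted over the list alone (adjusted p = 0.0012, or adjusted p = 0.18 with an estimated correlation). The miR-23 clusters had 2 of 3 lower, or 3 adjusted over the list alone (median -0.37, adjusted p = 0.020, or adjusted p = 0.31 with an estimated correlation). Under a slide block 33 miRNAs passed, and miR-551b was the 1 named miRNA of 20 that no longer did (adjusted p = 0.081), while all 20 kept their sign in both slide pairs. The medians of these 5 lists were the same under the block, where the miR-34 family passed as higher too (median 0.15, adjusted p = 0.042, or adjusted p = 0.48 with an estimated correlation).

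In 4TO7, miR-155 rose by 1.15 ± 0.05 from below detection on all 4 inhibitor arrays, at least 2.22-fold. MiR-181b rose by 0.98 ± 0.04, miR-181a by 0.90 ± 0.04, miR-22 by 0.62, miR-21 by 0.60 and miR-181d by 0.44. Rises were also measured for miR-140* (0.52), miR-140 (0.40), miR-16 (0.41) and miR-146a (0.45, at least 1.36-fold, detected on 2 of 4 TGF-beta arrays and on no inhibitor array). MiR-222 fell by 1.17 ± 0.05 and miR-221 by 1.16 ± 0.09. MiR-205, an epithelial miRNA, fell by 0.86 ± 0.05 (at least 1.81-fold, detected on no TGF-beta array and on 2 of 4 inhibitor arrays). MiR-193 and miR-26a each fell by 0.59, miR-365 by 0.55, miR-450a-5p by 0.47, miR-193b by 0.44, and miR-210 and miR-503 by 0.43. In all 35 miRNAs rose and 43 fell (27 and 53 under median scaling, 45 and 35 in the authors' value table), 3 of them more than 2-fold. The miR-181 family (3 of 4 higher, median 0.67, adjusted p = 0.00038, or adjusted p = 0.17 with an estimated correlation) and the TGF-beta induced list (2 of 8 higher, median 0.07, adjusted p = 0.026, or adjusted p = 0.17 with an estimated correlation) rose. The miR-30 family fell, with 3 of 5 lower, or 5 adjusted over the list alone (median -0.30, adjusted p = 0.022, or adjusted p = 0.35 with an estimated correlation). The miR-221 and miR-15 groups fell too, with 4 of 8 lower and miR-16 higher (median -0.22, adjusted p = 0.026, or adjusted p = 0.35 with an estimated correlation). A slide block left 63 miRNAs past the threshold, the 20 named ones among them, and these kept their sign in both slide pairs. Median shifts under the block were 0.67 for miR-181, 0.07 for the TGF-beta induced list, -0.28 for miR-30 and -0.21 for the miR-221 and miR-15 groups, and the Sfmbt2 cluster (-0.14, adjusted p = 0.042) and let-7 (-0.18, adjusted p = 0.0499) passed as lower, each with adjusted p = 0.80 with an estimated correlation. The miR-221 and miR-15 list lost its call with set number within each line as a block (adjusted p = 0.056), and the TGF-beta induced list without the detection filter (adjusted p = 0.17).

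In 4T1, miR-146a rose by 1.27 ± 0.06, miR-22 by 1.26 ± 0.06 and miR-146b by 0.998 ± 0.05, beside miR-181b (0.97 ± 0.04) and miR-181a (0.95 ± 0.04). Let-7i rose by 0.76, miR-132, a miRNA under control of the transcription factor CREB, by 0.74, miR-34a by 0.63 and miR-21 by 0.57. MiR-135b rose by 0.72, at least 1.65-fold, with detection on 3 of 4 TGF-beta arrays and no inhibitor array. MiR-210 fell by 1.23 ± 0.09, miR-222 by 1.11 ± 0.05 and miR-221 by 1.09 ± 0.09, followed by miR-193 (0.98), miR-365 (0.76), miR-193b (0.75), miR-31* (0.56), miR-100 (0.47), miR-15a (0.43) and miR-715 (0.43). In all 46 miRNAs rose and 70 fell, 5 of them more than 2-fold. The split was 77 and 55 in the authors' value table and 68 and 56 under median scaling over probes detected on all arrays. The miR-30 family (5 of 5 lower, median -0.36, adjusted p = 0.0029, or adjusted p = 0.23 with an estimated correlation) and the miR-221 and miR-15 groups (7 of 8 lower, median -0.42, adjusted p = 0.00021, or adjusted p = 0.17 with an estimated correlation) fell. The miR-181 family rose (3 of 4, median 0.68, adjusted p = 0.0011, or adjusted p = 0.23 with an estimated correlation). The Sfmbt2 cluster fell, with 9 of 15 lower (median -0.15, adjusted p = 0.0029, or adjusted p = 0.45 with an estimated correlation), and 3 or 4 lower in the authors' value table and under median scaling over probes detected on all arrays. No slide held both treatments of 1 microenvironment in 4T1, and with slide as a fixed block 50 miRNAs passed in place of 116, 48 of them shared. Of the 20 named miRNAs 18 still passed, and miR-15a (-0.36, adjusted p = 0.059) and miR-715 (-0.37, adjusted p = 0.24) did not. Median shifts under the block were -0.32 for miR-30, -0.27 for the miR-221 and miR-15 groups, 0.66 for miR-181 and -0.20 for the Sfmbt2 cluster.

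In all 3 lines miR-181a, miR-181b, miR-181d and miR-22 rose. In all 3 lines 15 miRNAs fell, namely let-7c, let-7e, miR-100, miR-125b-5p, miR-130a, miR-193, miR-193b, miR-210, miR-221, miR-222, miR-26a, miR-26b, miR-30a, miR-31* and miR-365. The lines were measured on separate arrays, but their tests share 1 estimate of the spread of each miRNA, so the calls are not independent between lines. Between 67NR and 4TO7, 6 higher and 16 lower calls were shared, where independent lists would share 1.15 and 3.30. Between 67NR and 4T1 the shared calls were 6 and 20 (1.51 and 5.37 for independent lists), and between 4TO7 and 4T1 they were 16 and 34 (4.41 and 8.25). Opposite calls were 1, 2 and 4.

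Whether the response to TGF-beta differed between lines was tested directly, and 53 miRNAs passed limma's F test. The 6 with the smallest p were miR-146a, miR-155, miR-146b, miR-149, miR-205 and miR-132, with adjusted p-values from 6.4e-08 to 1.2e-06 (8 arrays per line). MiR-146a rose by 1.27 in 4T1 and by at least 1.36-fold in 4TO7, and miR-146b rose in 4T1 by 0.83 ± 0.07 more than in 4TO7, where it was detected on 4 of 8 arrays. Neither was detected in 67NR, so no value is given for their response there. MiR-155, undetected on the inhibitor arrays of 4TO7, rose in that line by at least 1.10 more than in 67NR and at least 0.97 more than in 4T1, and its responses in 4T1 and 67NR differed by 0.13 ± 0.08 (adjusted p = 0.35). MiR-205 fell in 4TO7 by at least 1.81-fold and was detected on no array of the other lines. MiR-149 rose in 4T1 by 0.27 ± 0.04 more than in 4TO7, and it was detected on 1 of 8 arrays of 67NR. MiR-132 rose in 4T1 by 0.64 ± 0.07 more than in 4TO7, and in 67NR it was detected on the 4 inhibitor arrays and on no TGF-beta array. In a fit with a slide block 37 miRNAs passed this test, and 81 with set number within each line as a block.

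**Figure D2:**
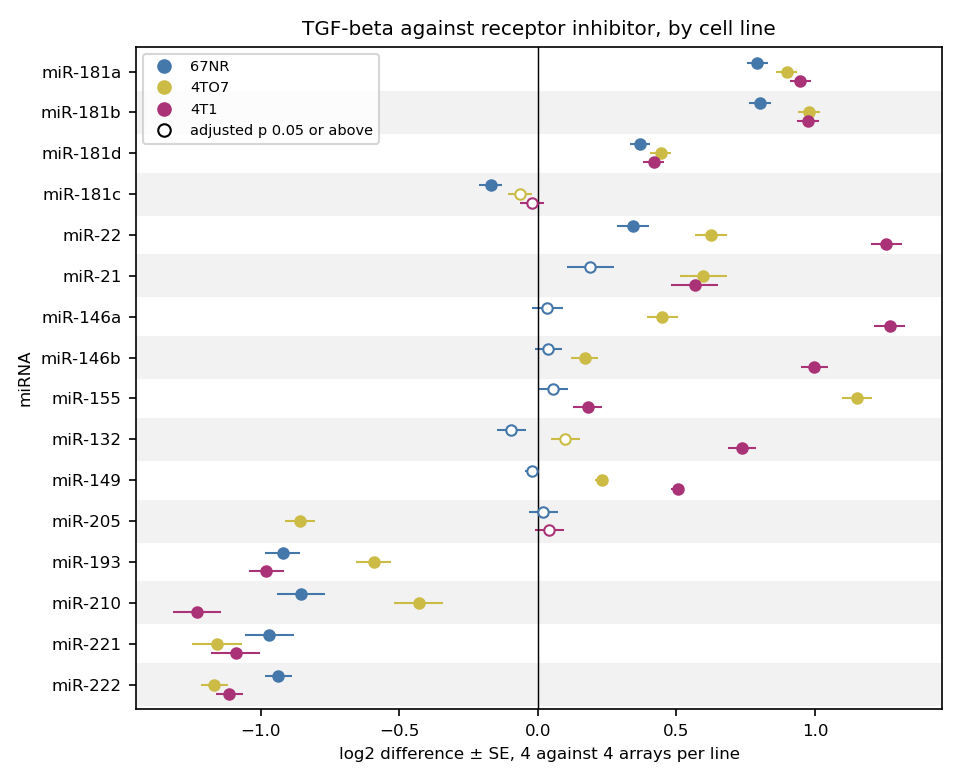
Log2 difference between TGF-beta and receptor inhibitor arrays for 16 miRNAs in each line, with error bars of 1 SE (4 arrays against 4) and open symbols for adjusted p of 0.05 or above. The differences of miR-181a lie between 0.79 and 0.95 in the 3 lines, while those of miR-155 are 0.05 in 67NR, at least 1.15 in 4TO7 and 0.18 in 4T1, and miR-146a, miR-146b and miR-205 in 67NR and miR-205 in 4T1 were below background on both sides.

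Whether the microenvironment changed the response to TGF-beta was tested by the difference between the effects on rigid and on compliant cultures (12 arrays each). No miRNA passed in limma (0 of 365), 22 had an unadjusted p under 0.05, and the smallest adjusted p was 0.59. The response of miR-181a was 0.94 ± 0.03 on compliant and 0.82 ± 0.03 on rigid cultures, a difference of -0.12 ± 0.04 (adjusted p = 0.67). The difference was 0.01 ± 0.05 for miR-181b. The 6 miRNAs with the smallest p had differences of -0.19 (miR-377, detected on 2 of 24 arrays), -0.18 (miR-500), 0.18 (miR-140*), -0.12 (miR-292-3p), -0.15 (miR-20b) and 0.17 (miR-132), none of which passed. None of the 18 lists tested passed, the smallest adjusted p being 0.79 (Sfmbt2 cluster, median 0.04).

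The next question was the effect of a rigid against a compliant microenvironment, over all lines with 12 arrays against 12. The inflammation-linked miR-146a and miR-146b fell on rigid cultures by 0.36 ± 0.03 (detected on 4 of 12 rigid and 6 of 12 compliant arrays) and 0.31 ± 0.03 (5 and 7 of 12), and miR-149 fell by 0.29 ± 0.01. MiR-210 fell by 0.26 ± 0.05, miR-9, a neural miRNA that also represses E-cadherin, by 0.24 ± 0.03, and miR-181a and miR-181b by 0.19 ± 0.02 and 0.15 ± 0.02. MiR-706 rose by 0.32 ± 0.03, and miR-16 and miR-195, cell cycle regulators of the same seed family, rose by 0.24 ± 0.05 and 0.19 ± 0.04. No change reached 2-fold.

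Other rises on rigid cultures were those of miR-218-2* (0.30), miR-574-5p (0.28), miR-431 (0.27), miR-466h (0.26), miR-466f-5p (0.25), miR-466f-3p (0.24) and miR-805 (0.22). Other falls were those of miR-715 (0.21), miR-221 (0.19), miR-205 (0.18, at least 1.13-fold) and miR-96 (0.18). Adjusted p-values of these named miRNAs ran from 6.8e-10 to 0.039, and 39 miRNAs rose and 41 fell in all (25 and 45 under median scaling over probes detected on all arrays). The miR-181 family fell (3 of 4, median -0.11, adjusted p = 0.0043, or adjusted p = 0.30 with an estimated correlation), as did the miR-183 cluster (2 of 3, median -0.18, adjusted p = 0.025, or adjusted p = 0.30 with an estimated correlation). The let-7 family passed with 1 of 9 lower (median -0.06, adjusted p = 0.025, or adjusted p = 0.68 with an estimated correlation). In the list of reported metastasis promoting miRNAs 4 of 8 fell, miR-9, miR-210, miR-222 and miR-221 (median -0.10, adjusted p = 0.025, or adjusted p = 0.42 with an estimated correlation). In the list of reported suppressing miRNAs 3 of 9 fell, miR-146a, miR-146b and miR-205 (median -0.05, adjusted p = 0.025, or adjusted p = 0.30 with an estimated correlation). The Sfmbt2 cluster had 6 of 15 higher and 1 lower, or 9 higher and 1 lower adjusted over the list alone (median 0.09, adjusted p = 0.025, or adjusted p = 0.70 with an estimated correlation). Of the lists that did not pass, 4 of 30 Dlk1-Dio3 members rose, 3 of 13 in the miR-17 clusters and 2 of 5 in the miR-30 family fell, and in the miR-221 and miR-15 groups 2 rose (miR-16, miR-195) and 2 fell. Among foreign markers, miR-208b fell by 0.15 and miR-128 by 0.10, and miR-129-3p rose by 0.08. MiR-214 of the fibroblast and mesenchymal list rose by 0.09.

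Rigid and compliant arrays of 1 line and treatment shared a slide in 3 cases, 2 in 4T1 and 1 in 4TO7, and in none for 67NR. Within them 85.0%, 86.3% and 81.3% of the 80 changed miRNAs moved in the same direction, with miR-706 at 0.35, 0.51 and 0.14 and miR-146a at -0.64, -0.99 and -0.12. Under a slide block the count fell to 39 (15 higher, 24 lower), and 16 of the 21 named miRNAs passed. Those that did not were miR-574-5p, miR-466f-3p, miR-195, miR-715 and miR-221, whose values under the block were 0.25, 0.23, 0.16, -0.19 and -0.18. Within slides the sign of miR-431, miR-715, miR-205 and miR-96 differed in at least 1 pair. List medians under the block were -0.11 for the miR-181 family (-0.10 to -0.06 within slides), -0.19 for the miR-183 cluster (-0.03, -0.26 and 0 in the 3 slide pairs), -0.12 for the promoting list (-0.18 to -0.16) and -0.04 for the suppressing list (-0.12 to 0.03). They were 0.08 for the Sfmbt2 cluster (-0.02 to 0.13) and -0.06 for let-7 (-0.13 to 0.05), which was no longer called (adjusted p = 0.065). The suppressing list lost its call in the authors' value table (adjusted p = 0.36) and with detection on at least 12 arrays required (adjusted p = 0.28).

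By line, the rigid culture of 67NR (4 arrays against 4) had 23 miRNAs higher and 17 lower. MiR-466h rose by 0.64 ± 0.11, miR-466f-5p by 0.63 ± 0.10, miR-574-5p by 0.54 ± 0.12, miR-706 by 0.45 ± 0.04, miR-431 by 0.43, miR-466f-3p by 0.37 and miR-193b by 0.30. MiR-297a and miR-466d-5p rose by at least 1.20-fold and 1.23-fold. MiR-208b fell by 0.39, miR-181a by 0.32 ± 0.04, miR-181b by 0.27 ± 0.04, miR-9 by 0.27, miR-181d by 0.23, miR-182 by 0.23, miR-467e by 0.22, miR-149 by at least 1.17-fold and miR-423-5p by 0.21. MiR-669a and miR-96 passed too, but were below background on both sides. The Sfmbt2 cluster rose, with 9 of 15 higher (2 of these, miR-669a and miR-669b, below background in 67NR) and 1 lower, or 12 higher and 1 lower adjusted over the list alone (median 0.28, adjusted p = 1.3e-06, or adjusted p = 0.47 with an estimated correlation). The miR-181 family fell (3 of 4, median -0.25, adjusted p = 0.00019, or adjusted p = 0.34 with an estimated correlation). Blocking by slide left 32 miRNAs past the threshold, the 20 named ones among them, and these medians were 0.30 and -0.24. The miR-183 cluster passed as lower only under this block (median -0.27, adjusted p = 0.033, or adjusted p = 0.48 with an estimated correlation), and 2 of its 3 members, miR-183 and miR-96, were below background in 67NR, so this is not evidence of a fall of the cluster.

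In 4TO7 the rigid culture had 3 miRNAs higher, miR-805 (0.31 ± 0.05), miR-708 (0.25) and miR-882 (0.17), and 7 lower (5 and 7 in the authors' value table, 3 and 14 under median scaling over probes detected on all arrays). Without single arrays the count of 10 ranged from 7 to 18, and it was 18 with set number within each line as a block. MiR-205 fell by 0.59 ± 0.05 (at least 1.5-fold), miR-210 by 0.56, miR-9 by 0.28, miR-31* by 0.24, miR-148a by 0.18, miR-149 by 0.17 and miR-99a by 0.16. MiR-181a and miR-181b differed by -0.07 (adjusted p = 0.38) and -0.11 (adjusted p = 0.16). The promoting list fell, with 2 of 8 lower, or 4 lower and 1 higher adjusted over the list alone (median -0.10, adjusted p = 0.029, or adjusted p = 0.45 with an estimated correlation). The suppressing list passed with 1 of 9 lower, or 3 adjusted over the list alone (median -0.04, adjusted p = 0.029, or adjusted p = 0.38 with an estimated correlation). That call was lost in the authors' value table (adjusted p = 0.24) and with detection on at least 12 arrays required (adjusted p = 0.24). Blocking by slide left 7 miRNAs, and miR-882, miR-31*, miR-148a and miR-99a of the 10 did not, while the promoting and suppressing lists had medians of -0.13 each. Under the block the Sfmbt2 cluster also passed as lower (median -0.12, adjusted p = 0.00027, or adjusted p = 0.65 with an estimated correlation), but its median was -0.01 without the block and -0.02 in the 1 slide pair, and no member was called. The miR-34 family passed as higher under the block (median 0.13, adjusted p = 0.017, or adjusted p = 0.65 with an estimated correlation).

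In 4T1 the rigid culture had 13 miRNAs higher and 14 lower (11 and 18 in the authors' value table), and without single arrays the count of 27 ranged from 14 to 33. MiR-146a fell by 0.80 ± 0.06, miR-146b by 0.66 ± 0.05, miR-149 by 0.49 ± 0.02, miR-221 by 0.31, miR-222 by 0.29, miR-484 by 0.26, miR-125b-5p by 0.25, miR-125a-5p and miR-99a by 0.22, and miR-181a by 0.17. MiR-181b differed by -0.06 (adjusted p = 0.41). MiR-16 rose by 0.53 ± 0.09, miR-218-2* by 0.49, miR-706 by 0.44 ± 0.04, miR-805 by 0.41, miR-431 and miR-195 by 0.40, miR-483 by 0.25, miR-301b by 0.21, and miR-30c-2* and miR-696 by 0.18. No list passed, the smallest adjusted p being 0.051. Blocking by slide left 12 miRNAs in place of 27, and 11 of the 20 named ones. Those lost were miR-431, miR-483, miR-30c-2*, miR-696, miR-221, miR-484, miR-125b-5p, miR-125a-5p and miR-181a (block adjusted p = 0.056 to 0.13), all of which kept their sign in both slide pairs. Under the block the promoting list passed as lower (median -0.20, adjusted p = 0.017, or adjusted p = 0.57 with an estimated correlation) and the Sfmbt2 cluster as higher (median 0.09, adjusted p = 0.044, or adjusted p = 0.59 with an estimated correlation). With the 4T1 arrays fitted alone, 10 miRNAs passed.

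An F test of whether the effect of rigidity differed between lines, chosen after the values were seen, passed for 30 miRNAs, or for 14 to 38 without single arrays. MiR-149 fell by 0.49 in 4T1, by 0.17 in 4TO7 and by at least 1.17-fold in 67NR, where it was below background on most arrays. MiR-146a and miR-146b fell by 0.80 and 0.66 in 4T1 and were below background in 67NR, and in 4TO7 miR-146a (detected on 2 of 8 arrays) and miR-146b (on 4 of 8) did not pass. MiR-205 fell by at least 1.5-fold in 4TO7 and was below background in the other lines. For these 3 miRNAs, and for miR-149 in 67NR, the F test compares signals that were partly at background. MiR-805 differed by -0.05 in 67NR, 0.31 in 4TO7 and 0.41 in 4T1, and miR-706 by 0.45, 0.08 and 0.44 in the same order.

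**Figure D3:**
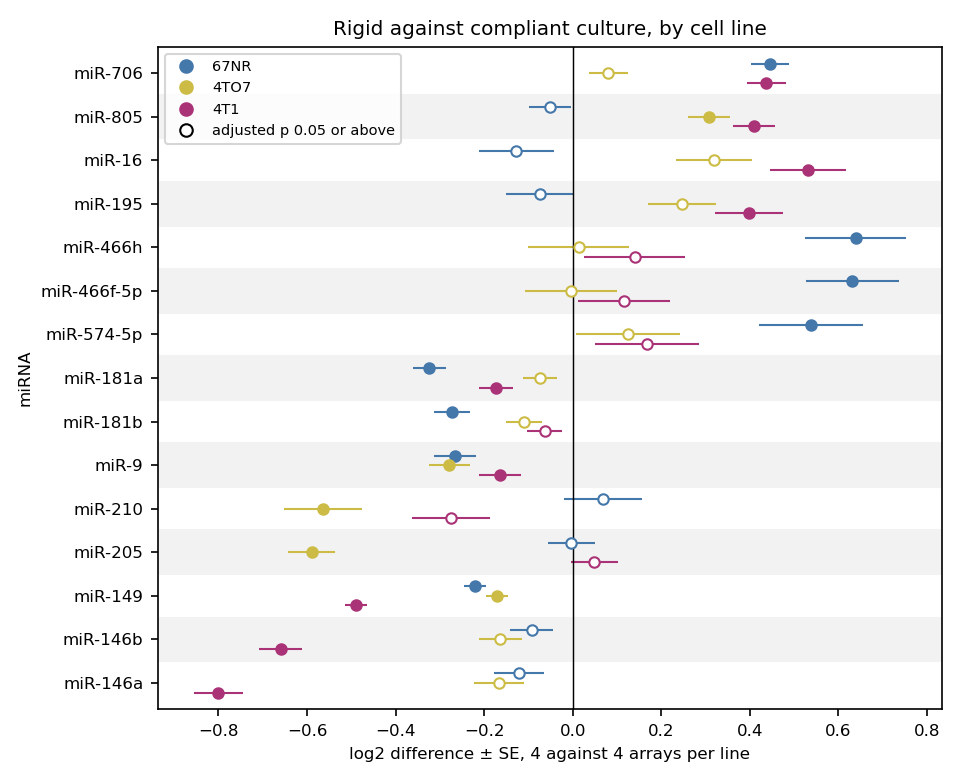
Log2 difference between rigid and compliant arrays for 15 miRNAs in each line, with error bars of 1 SE (4 arrays against 4) and open symbols for adjusted p of 0.05 or above. MiR-146a lies at -0.80 in 4T1, and miR-466h at 0.64 in 67NR, while miR-146a, miR-146b and miR-205 in 67NR and miR-205 in 4T1 were below background on both sides.

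The last comparisons set the lines against each other with 8 arrays each, from the nonmetastatic 67NR to the invasive and metastatic lines. In 4TO7, miR-182 was 2.79 ± 0.04 higher than in 67NR (6.90-fold) and miR-96 was 2.75 ± 0.05 higher (at least 6.61-fold), both from the miR-183 cluster of sensory and tumour miRNAs. Members of the oncogenic miR-17 clusters followed, with miR-19b higher by 2.53 ± 0.04, miR-17 by 2.34, miR-20a by 2.28, miR-18a by 1.84 (at least 2.54-fold), miR-92a by 1.72 and miR-106a by 1.71. MiR-210 was higher by 1.70 ± 0.06 and the probe shared by miR-467a and miR-467b by 1.87 (at least 3.66-fold). MiR-7a was lower by 1.28 ± 0.03, miR-22 by 1.12 ± 0.04, and miR-143 and miR-145, miRNAs of smooth muscle and mesenchyme, by 1.09 ± 0.03 (at least 2.02-fold) and 0.88 ± 0.04. MiR-712* was lower by 1.16, miR-715 by 0.87, miR-494 by 0.80, miR-761 by 0.78, miR-34a by 0.72, miR-204 by 0.70, miR-181a by 0.26 and miR-181b by 0.22. In all 109 miRNAs were higher and 208 lower, 28 of them more than 2-fold (24 higher and 4 lower).

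The median of all tested miRNAs was itself shifted by -0.15 between 4TO7 and 67NR, by -0.22 between 4T1 and 67NR and by -0.07 between 4T1 and 4TO7. It was -0.18, -0.28 and -0.10 under median scaling and -0.12, -0.16 and -0.04 in the authors' value table, so list medians are also given relative to it. In 4TO7 against 67NR, all 13 measured miR-17 members were higher (median 1.57, relative 1.72, adjusted p = 7.5e-10, or adjusted p = 0.038 with an estimated correlation), and the median was 1.21 with the 5 members undetected on 1 side at their bound. Of 30 tested Dlk1-Dio3 members 28 were lower and none higher (median -0.26, relative -0.11, adjusted p = 0.0034, or adjusted p = 0.032 with an estimated correlation). Its median was close to those of the embryonic stem cell (-0.27) and the neural and liver list (-0.29), smaller lists of foreign markers that did not pass. All 3 members of the miR-183 cluster (relative median 2.90, adjusted p = 0.0034) and of the miR-29 family, which represses collagen genes, were higher (relative median 1.68, adjusted p = 0.0072), each with adjusted p = 0.13 with an estimated correlation. All 5 tested miR-30 members were higher (relative median 0.62, adjusted p = 0.0048, or adjusted p = 0.13 with an estimated correlation). In the let-7 family 8 of 9 were higher and 1 lower (relative median 0.63, adjusted p = 0.0036, or adjusted p = 0.24 with an estimated correlation). In the miR-23 clusters 3 of 3 were higher (relative median 0.83, adjusted p = 0.032, or adjusted p = 0.24 with an estimated correlation). In the miR-221 and miR-15 groups 7 of 8 were higher and 1 lower (relative median 0.51, adjusted p = 0.025) and in the promoting list 6 of 8 were higher and 2 lower, led by miR-210 and miR-9 (relative median 0.66, adjusted p = 0.025), each with adjusted p = 0.24 with an estimated correlation. In the Sfmbt2 cluster 8 of 15 were higher and 2 lower (relative median 0.30, adjusted p = 0.0035, or adjusted p = 0.29 with an estimated correlation).

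Lists with lower members in 4TO7 against 67NR included the fibroblast and mesenchymal list and markers of foreign cell types. All 6 tested fibroblast and mesenchymal markers, among them miR-143, miR-145, miR-199a-5p (-0.53) and miR-214 (-0.57), were lower (relative median -0.40, adjusted p = 0.025, or adjusted p = 0.13 with an estimated correlation). The TGF-beta induced list, which shares miR-143, miR-145, miR-199a-5p and miR-10b with it, had 7 of 8 lower and 1 higher (relative median -0.30, adjusted p = 0.047, or adjusted p = 0.13 with an estimated correlation). Embryonic stem cell miRNAs (6 of 6 lower, relative median -0.11, adjusted p = 0.10) and neural and liver miRNAs (5 of 6 lower, 1 higher, relative median -0.13, adjusted p = 0.17) did not pass the list test, nor did the miR-34 family with 6 of 6 lower and the miR-181 family with 3 of 4 lower. MiR-206 of muscle was lower by at least 1.58-fold and miR-208b differed by -0.07. Arrays of 4TO7 and 67NR from the same microenvironment and treatment shared a slide in 3 cases, in which 96.8% to 97.5% of the 317 miRNAs kept their direction. Under a slide block 299 passed, including all 22 named, with list medians of 1.53 for miR-17 (1.44 to 1.65 within slides), -0.26 for Dlk1-Dio3 (-0.29 to -0.23), 2.70 for miR-183 (2.70 to 2.99), 1.54 for miR-29 (1.23 to 1.54), 0.49 for let-7 (0.39 to 0.54), 0.48 for miR-30 (0.44 to 0.64), -0.45 for the TGF-beta induced list (-0.67 to -0.49) and -0.56 for the fibroblast list (-0.64 to -0.53). With the block and an estimated correlation, miR-17 and Dlk1-Dio3 no longer passed (camera adjusted p = 0.094 and 0.079). Several list calls made at the preset correlation were lost under 1 or more alternatives. They were miR-23 (adjusted p = 0.056, scaling over probes detected on all arrays), the TGF-beta induced list (0.055 without the detection filter, 0.11 with detection on at least 12 arrays required), the fibroblast list (0.065, the stricter filter) and the promoting list (0.058, scaling over probes detected on all arrays).

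In 4T1, the highly metastatic line, the miR-200 family, which maintains the epithelial state by repressing ZEB transcription factors, stood far above 67NR. MiR-200c was higher by 2.84 ± 0.04 (at least 6.41-fold), miR-141 by 2.48 ± 0.04 and miR-200a by 2.21 ± 0.04. MiR-182 was higher by 2.89 ± 0.04 (7.44-fold), miR-96 by 2.85 ± 0.05 (at least 7.10-fold), miR-17 by 2.77 ± 0.04, miR-19b by 2.65, miR-20a by 2.53, miR-18a by 2.18 (at least 3.21-fold) and the miR-467a and miR-467b probe by 2.09 (at least 4.25-fold). MiR-181a and miR-181b were higher by 0.95 ± 0.03 and 0.61 ± 0.03. MiR-7a was lower by 1.18, miR-204 by 1.15, miR-211 by 1.11, miR-145 by 1.08, miR-143 by 1.07 (at least 2.04-fold), miR-494 by 0.90, miR-761 and miR-214 by 0.88, miR-505 by 0.82 and miR-135a* by 0.79. In all 112 miRNAs were higher and 215 lower, 45 of them more than 2-fold (40 higher and 5 lower). These differences share the 8 arrays of 67NR with those of 4TO7.

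**Figure D4:**
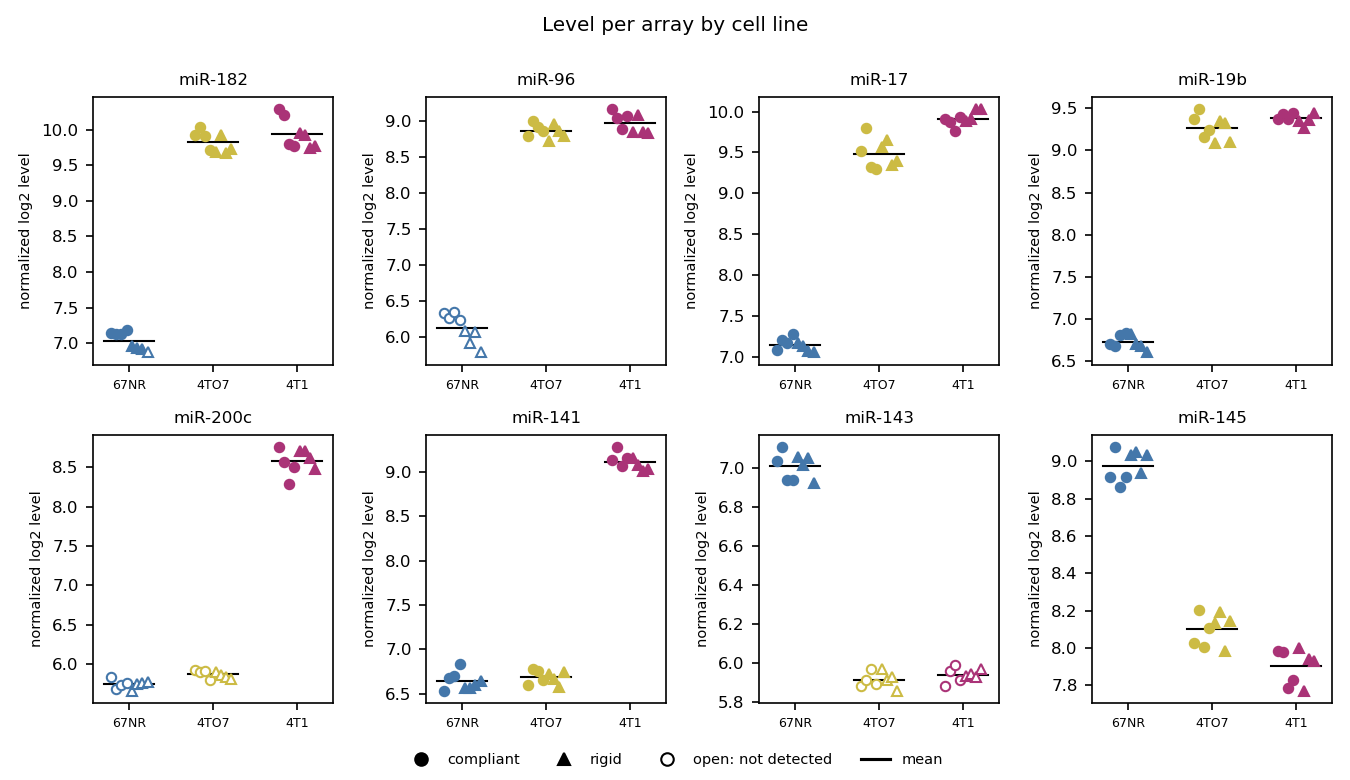
Normalized log2 level of 8 miRNAs by line, treatments pooled, with 1 point per array (circles compliant, triangles rigid, open symbols not detected) and a bar at the mean. MiR-200c lies at least 6.41-fold higher in 4T1 than in 67NR and at least 6.13-fold higher than in 4TO7, and miR-182 is higher in both 4TO7 (2.79) and 4T1 (2.89) than in 67NR.

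Among the lists in 4T1 against 67NR, 5 of 5 miR-200 members (median 2.21, relative 2.43, adjusted p = 0.00029, or adjusted p = 0.045 with an estimated correlation) and 13 of 13 miR-17 members were higher (median 1.86, relative 2.08, adjusted p = 2.7e-08, or adjusted p = 0.045 with an estimated correlation). The miR-17 median was 1.35 with the 5 members undetected on 1 side at their bound. All 4 miR-181 members were higher (relative median 1.20, adjusted p = 0.0040), as were the 5 tested of miR-30 (relative 0.84, adjusted p = 0.0061), each with adjusted p = 0.16 with an estimated correlation. All 3 of the miR-183 cluster (relative 3.07, adjusted p = 0.0051, or adjusted p = 0.15 with an estimated correlation) and of the miR-29 family were higher (relative 1.38, adjusted p = 0.021, or adjusted p = 0.17 with an estimated correlation). All 9 let-7 members (relative 0.74, adjusted p = 0.0014), all 3 of the miR-23 clusters (relative 1.45, adjusted p = 0.021) and 7 of 8 in the promoting list, with 1 lower (relative 0.64, adjusted p = 0.019), were higher, each with adjusted p = 0.20 with an estimated correlation. The Sfmbt2 cluster had 8 of 15 higher and 3 lower (relative 0.28, adjusted p = 0.020, or adjusted p = 0.41 with an estimated correlation). In the Dlk1-Dio3 cluster 24 of 30 were lower and none higher (median -0.40, relative -0.19, adjusted p = 0.0040, or adjusted p = 0.045 with an estimated correlation). The smaller embryonic stem cell and neural and liver lists had medians close to it, -0.38 and -0.36, without passing. In the fibroblast and mesenchymal list 6 of 6 were lower (relative -0.55, adjusted p = 0.028, or adjusted p = 0.16 with an estimated correlation), a call lost with detection on at least 12 arrays required (adjusted p = 0.079). Embryonic stem cell miRNAs (6 of 6 lower, relative -0.17, adjusted p = 0.094), neural and liver miRNAs (5 of 6 lower, relative -0.14, adjusted p = 0.12) and the miR-34 family (6 of 6 lower) did not pass the list test. MiR-206 of muscle was lower by at least 1.60-fold, miR-208b by 0.36 and miR-451 of blood by 0.28. Slides shared by matched arrays gave 96.6% and 98.5% of the 327 miRNAs in the same direction. Under a slide block 326 passed, with medians of 2.20 for miR-200 (2.04 to 2.27 within slides), 1.87 for miR-17 (1.80 to 1.88), -0.40 for Dlk1-Dio3 (-0.45 to -0.40) and -0.76 for the fibroblast list (-0.92 to -0.63). With the block and an estimated correlation, miR-200, miR-17 and Dlk1-Dio3 no longer passed (camera adjusted p = 0.090, 0.0996 and 0.090).

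Between the 2 more aggressive lines, 4T1 stood out by the miR-200 family. MiR-200c was higher by 2.71 ± 0.04 (at least 6.13-fold), miR-141 by 2.43, miR-200a by 2.14, miR-429 by 2.09 (at least 3.21-fold) and miR-200b by 1.94 (at least 2.81-fold). The miR-181 family was higher as well, with miR-181a at 1.21 ± 0.03 (2.32-fold), miR-181c at 1.18, miR-181d at 1.13 and miR-181b at 0.83, beside miR-146a (1.60 ± 0.04, detected on 8 against 2 arrays) and miR-125b-5p (1.09). MiR-148a and miR-205 were lower by 0.82 each (at least 1.77-fold and 1.75-fold), miR-210 by 0.78, miR-322 by 0.58, miR-99b by 0.52, miR-350 by 0.51, miR-693-5p by 0.49, miR-211 by 0.46, miR-204 by 0.45 and miR-489 by at least 1.16-fold. In all 84 miRNAs were higher and 146 lower (69 and 194 under median scaling, 70 and 190 over probes detected on all arrays), 11 of them more than 2-fold (11 higher and 0 lower). The miR-200 family (5 of 5 higher, relative median 2.21, adjusted p = 1.6e-08, or adjusted p = 0.0062 with an estimated correlation) and the miR-181 family (4 of 4 higher, relative 1.22, adjusted p = 7.5e-06, or adjusted p = 0.074 with an estimated correlation) passed. So did the miR-17 clusters (10 of 13 higher, relative 0.21, adjusted p = 0.0014) and the miR-23 clusters (3 of 3 higher, relative 0.63, adjusted p = 0.030), each with adjusted p = 0.33 with an estimated correlation. In lists that did not pass, 14 of 30 Dlk1-Dio3 members were lower and 2 higher, 3 of 3 in the miR-29 family and 6 of 8 in the miR-221 and miR-15 groups were lower, and 3 of 6 fibroblast and 3 of 6 embryonic stem cell markers were lower. With slide as a block 184 passed, including the 21 named, with medians of 2.09 for miR-200 (2.01 to 2.27 within slides) and 1.155 for miR-181 (1.13 to 1.15). By detection, miR-143 and miR-206 were found on all 8 arrays of 67NR and on no other array, miR-148a on all 8 of 4TO7 and no other, and miR-200b, miR-200c and miR-429 on all 8 of 4T1 and no other.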

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

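Of the tests below, the F test of rigidity between lines with its permutations, both miR-181 tests, the tests on the miRNAs with the highest levels, the spike-in test for 4TO7, the residual correlations and the choice of the GU-repeat set came after the results were seen. So did the rule that probes at the floor decide nothing.

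Other splits of the same arrays were fitted with the label and the other factors, per line on that line's 8 arrays, so their real counts differ from those reported. For TGF-beta over all lines, 1 of 100 splits, the real one, gave as many as its 130 miRNAs, and the highest other split, which shared 20 of 24 arrays with it, gave 116. The same held for 1 of 34 splits in 67NR (37, highest other 1), 4TO7 (74, highest other 0) and 4T1 (95, highest other 0). For rigidity, the real split alone reached its count over all lines (1 of 100, 63 against 1) and, at 1 of 34 each, in 67NR (33 against 3), 4TO7 (8 against 1) and 4T1 (8 against 0). For the lines it was 1 of 100 each, with 311 against 256 for 4TO7 and 67NR, 322 against 301 for 4T1 and 67NR, and 215 against 158 for 4T1 and 4TO7. For these 11 comparisons only the real split reached its count, which argues against chance division of the arrays within the 34 or 100 splits fitted.

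The response to TGF-beta differed between the lines for 53 miRNAs by the F test of the difference. Of 100 permutations of treatment within line and microenvironment, 2, the real one included, called as many (57, highest other 64). Exchanging treatments in some groups carries the TGF-beta effect itself into such a difference, so these permutations cannot exclude chance. The F statistics were 126 for miR-146a, 126 for miR-155, 115 for miR-146b, 111 for miR-149, 91.0 for miR-205 and 70.9 for miR-132. The effect of rigidity differed between lines for 30 miRNAs, led by miR-149 (F 47.5), miR-146a (46.2), miR-205 (43.5), miR-146b (40.5), miR-805 (25.7) and miR-706 (22.7). Of 100 permutations of microenvironment, 1, the real one, called as many (32, highest other 30). These permutations likewise carry the effect of rigidity itself into the difference, so they cannot exclude chance either. For the difference of the TGF-beta effect between microenvironments, with 0 passing, all 100 permutations reach that count by construction, so there is no result for which chance would need to be excluded. The highest other called 53, and a permutation that exchanges treatments in some groups carries the TGF-beta effect itself into the difference, a structure of the samples. The probes for miR-202-5p and miR-689 were left out of the tests because their fail code was set on 24 of 24 arrays, yet both were detected on 24. Fitted with the rest, miR-202-5p was lower in 4T1 than in 67NR by 0.56 ± 0.08 (limma adjusted p = 5.2e-06) and miR-689 was higher by 0.21 (adjusted p = 0.0077). Groups of 2 arrays were too small for a gap test of single deviating arrays, and fits without single arrays are given with the alternatives.

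MiR-181d rose with TGF-beta by 0.41 while miR-181c, encoded beside it in the genome, did not rise. MiR-181c lay at -0.0850 ± 0.025, which would argue against an equal change of 1 shared transcript if the rise of miR-181d were its own, and until that is known equal and unequal change cannot be told apart. Cross-hybridisation of miR-181b to the miR-181d probe stays open. On the linear scale the rise of miR-181d was 0.341, 0.363 and 0.423 of that of miR-181b in 67NR, 4TO7 and 4T1, a spread of 0.0814 (SE 0.064) consistent with a constant share. Different stability of the mature miRNAs was not tested.

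Most tested miRNAs were lower in 4T1 and 4TO7 than in 67NR, with medians of -0.22 and -0.15. Changes of more than 2-fold went mostly the other way, with 40 higher and 5 lower in 4T1 and 24 and 4 in 4TO7. Lower calls were not confined to low signals. The 91 miRNAs with the highest levels had medians of -0.169 (bootstrap SE 0.064) in 4T1 and -0.123 (0.058) in 4TO7, each more than 2 bootstrap SE below 0. Among them 29 were called higher and 49 lower in 4T1, and 31 and 46 in 4TO7. The bootstrap drew miRNAs measured on the same arrays, so its SE measures no spread between arrays. The test therefore cannot exclude background as the sole cause. The 166 probes without a fail code that were detected on no array had medians of -0.0788 in 4T1 (126 lower) and -0.0607 in 4TO7 (129 lower). Against medians of the lower calls of -0.375 and -0.271, these met the bound set beforehand against a shift of all signals. But these probes lie at the floor (median level 6.19, against 8.12 for tested ones), so a shift of all signals and lower miRNA levels cannot be told apart. Setting the bound aside for this reason came after the values were seen. Scaled to the spike-in probes, the medians were -0.193 ± 0.093 in 4T1, just over 2 SE below 0, and -0.363 ± 0.080 in 4TO7. But 3 and 5 of 32 spike-in probes themselves passed in these comparisons, with differences of up to 0.32 and 0.49. Scaling to them therefore cannot exclude scaling between arrays as the sole cause. A difference between the lines stays open as untested, and so does the reason why 12 embryonic stem cell, neural and liver miRNAs, which these lines are not known to express, were lower too (medians -0.373 ± 0.044 and -0.278 ± 0.038).

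In 67NR, 17 miRNAs with GU-repeat sequences, 10 of them called higher (miR-669a and miR-669b among these below background in 67NR) and 1 lower, had a median of 0.278 on rigid against compliant cultures, or 0.281 over the 13 detected in this line. A single array is argued against, since the median was at least 0.231 ± 0.042 without each of the 8 arrays. Leaving out 1 array cannot exclude a rise carried by 1 replicate set, which stays open. In set 1 the median levels of these miRNAs overlapped, at 7.2718 and 7.1845 on rigid and 7.208 and 7.2348 on compliant arrays. In set 2 they were 7.3751 and 7.3264 on rigid against 7.0682 and 6.9953 on compliant arrays. Slide is argued against too, with a median of 0.303 under a slide block. But no slide held both microenvironments of 1 treatment in this line. Also left open is 1 shared signal, such as a repeat-containing RNA, that may have been read by all of these probes. Their residuals correlated at a median of 0.566, where the 95th percentile of 1000 random sets was 0.068. In 4TO7 and 4T1 the medians were -0.01 and 0.07, and the fall of the Sfmbt2 cluster in 4TO7 (median -0.12, camera adjusted p = 0.00027) rests on the slide block and the preset correlation alone (-0.01 without the block, -0.02 within 1 slide), so a response of this locus to rigidity stays open.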

How the results depend on the processing

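Median scaling over probes detected on all arrays, keeping fail-coded probes, and the F test of rigidity between lines were chosen after the data were seen. The 239 named values were recomputed under each alternative in which they were tested, which gave 8489 values. Of these, 8284 kept direction and side of the threshold, 197 kept the direction and lost the call, 1 gained it and 7 reversed. The rise of miR-181a with TGF-beta stayed between 0.830 (median scaling) and 0.889 (the authors' value table). Counts stayed within 1.5 times the reported ones except as follows, and the cause was not tested unless given. For TGF-beta in 67NR (40 reported), 61 passed in the authors' value table and 63 with array weights. With slide as a fixed block, 50 passed in place of 116 for TGF-beta in 4T1 (48 shared), 39 in place of 80 for rigidity over all lines (38 shared) and 12 in place of 27 for rigidity in 4T1. Slides and groups overlap in this design, so the block removes part of the contrast by construction. For rigidity in 4TO7 (10 reported) 17 passed under median scaling over probes detected on all arrays, and for rigidity in 4T1 10 passed with only the lines compared, where fewer arrays enter the fit. With a replicate block of set number within each line, 70 miRNAs passed for TGF-beta in 67NR, 18 for rigidity in 4TO7 and 81 in place of 53 for the TGF-beta effect between lines. In 4T1, where the pairing of sets was seen in the residuals, that replicate block gave 135 in place of 116 for TGF-beta and 30 in place of 27 for rigidity. In 67NR and 4TO7 residuals of the same set were correlated above 0.1 in 2 and 3 of 6 pairs of groups. With camera's estimated correlation 6 pairs of list and comparison passed in place of 57, and 1 with the slide block added, the miR-200 family in 4T1 against 4TO7, for a reason that was not tested. Over the other alternatives 51 to 62 passed. The direction of a list's median flipped with the scaling for the miR-200 family and the miR-23 clusters on rigid 4T1 cultures, the promoting list for TGF-beta in 67NR and muscle miRNAs in 4TO7 against 67NR, none of which had passed. Leaving out single arrays, with the lone array of that group assumed to vary like the others, gave 7 to 18 miRNAs for rigidity in 4TO7 (18 without replicate 1 or replicate 2 of 4T1 compliant basal). It gave 14 to 33 for rigidity in 4T1 (14 without replicate 2 of 4T1 compliant TGF-beta, 17 without replicate 1 of 4T1 rigid basal). It gave 14 to 38 in place of 30 for the rigidity effect between lines (18 without replicate 1 of 67NR compliant basal, 16 without replicate 2 of 4TO7 compliant basal, 17 and 14 without replicate 2 of 67NR rigid basal and of 67NR rigid TGF-beta). For the TGF-beta effect between microenvironments it gave 0 to 1 (1 without replicate 2 of 4T1 rigid TGF-beta). The other counts ranged from 127 to 157 for TGF-beta over all lines, 28 to 47 in 67NR, 61 to 81 in 4TO7 and 91 to 139 in 4T1, and from 57 to 91 for rigidity over all lines. The difference of miR-181b between the TGF-beta effects on rigid and compliant cultures, 0.01 and not passing, changed sign to -0.0327 under median scaling and -0.0387 in the authors' value table. Without single arrays it lay between -0.0128 and 0.0322, below 0 for replicate 1 of 67NR compliant TGF-beta, 4T1 compliant TGF-beta, 4TO7 rigid basal, 67NR rigid TGF-beta and 4TO7 compliant basal. Signal over background limits miRNAs near the detection limit, whose folds are given as bounds. Background correction and probes of other species could not be varied and were not run.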

Other observations

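The test of neighbouring genes was set before its result was seen. The test with the Dlk1-Dio3 region left out, and a widening of the seed families to merge miRNAs that share most of a seed, were chosen after.

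A hypothesis was that miRNA genes lying close together change together because they may share transcription. Of 294 miRNAs with mapped names, 264 were matched to genes of the GRCm38.p6 annotation. Of these, 158 pairs of 78 miRNAs lay within 10000 bp of each other and were assigned to different seed families. Their sequences were not compared further, so cross-hybridisation between the probes of some neighbours stays open. For TGF-beta, the mean absolute difference between the effects of neighbours was 0.0848, against 0.187 with effects permuted, with a one-sided permutation p = 1e-04, the smallest that 10000 permutations can give. For rigidity it was 0.0642 against 0.0959 (permutation p = 0.0018). An alternative is that neighbours share low levels and so small changes. With the Dlk1-Dio3 region left out and effects permuted only within 5 bins of like level, 49 pairs still differed less than permuted ones for TGF-beta (0.0932 against 0.186, permutation p = 0.0022). This argues against low levels as the sole cause, as far as 5 bins match them. The measure is also small where neither neighbour responds, so it does not by itself show that neighbours change together. Pairs of neighbours share miRNAs and are not independent.

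Among the neighbours, miR-193b and miR-365 both fell with TGF-beta by 0.63, miR-99a and let-7c by 0.28 and 0.25 and miR-100 and let-7a by 0.37 and 0.13. The neighbours miR-26a and miR-546 differed, at -0.40 and 0.09, as did let-7e and miR-99b, at -0.23 and 0.05. The signs were equal in 99 of the 158 pairs and in 30 of the 49.

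Across the 365 miRNAs, TGF-beta effects correlated between lines at Pearson r = 0.595 and Spearman rho = 0.358 for 67NR and 4TO7, 0.678 and 0.543 for 67NR and 4T1, and 0.686 and 0.570 for 4TO7 and 4T1. These are 3 correlations across miRNAs, which are not independent replicates.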
